A study of Mus musculus with 24 samples.

How the data were processed

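Gene expression was measured in sorted fractions of mouse embryoid bodies, the aggregates in which embryonic stem cells differentiate in culture. Per the labels, the cells were of the Ainv15 line and carried a doxycycline-inducible ICN1, the intracellular domain of Notch1. ICN1 was induced from day 3 to day 5 or not at all, and on day 6 the cells were dissociated and sorted into fractions named CD41 sp, VE sp, DP and DN. The labels do not spell these names out. The 2 conditions and 4 fractions made 8 groups of 3 replicates, 24 Illumina arrays in all. RNA was extracted with an RNeasy kit and labelled as biotinylated cRNA with a MessageAmp kit, per the labels' protocols. The nature of the replicates is not stated, so p-values measure the spread between these samples, which may be partly technical. Doxycycline was given with every induction, so the effects of the drug and of ICN1 cannot be separated in this design.

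Each replicate set of 8 arrays came in 1 table, 3 tables in all. The deposited tables held the probe intensity on a linear scale, which per the file headers was not normalized and had no background subtracted. They also held a detection p-value for each probe and array, per the file headers, in steps of 1/798 by their values. A further table held the authors' processed intensities. These were on a linear scale and not centred, and their correlation with the raw values on the log2 scale was 0.991 to 1.00 over the arrays. Their column medians were 78.66 to 78.73, 59.87 to 59.90 and 66.86 to 66.92 in replicate sets 1, 2 and 3. Normalization within each set only would give this. The method behind them is not given in the sources used here, so they served as an alternative. The mean raw intensity of an array ranged from 165 to 656, and between 41.8% and 51.3% of the 25697 probes were detected at a detection p under 0.05. The number of arrays limits the precision.

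Signals were background-corrected with neqc of limma 3.58.1 in R 4.3.3, with the negative-control level taken from the detection p-values because no control probes were given. An offset of 16 was added and the arrays were quantile-normalized. Probes with a detection p under 0.05 on all 3 arrays of at least 1 group were kept (12894 probes). For each gene symbol the probe with the highest mean signal was used, which left 9591 of 18120 symbols. The symbols are those of the array design. Of the tested ones, 9275 matched a current symbol or synonym in a RefSeq table of assembly GRCm38.p6 that was used for names only. No genome was used here, so no coordinates are given.

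Group means were fitted with limma's lmFit and eBayes on all 24 arrays, with 8 group means, no block and 16 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, without a fold threshold. Induced and non-induced cells were compared within each fraction and on average over the 4 fractions, and an F test over 3 contrasts asked whether the response differed among fractions. The non-induced fractions were compared in 5 pairs, and those set against DN share its 3 arrays. Changes are log2 differences with limma's standard error, and p-values are limma's adjusted p. A probe not detected on any array of a group has only an upper bound there. Such changes are given as at least N-fold, the mean of the brighter group over the mean, for each array of the dimmer group, of the higher of the lowest detected signal and the probe's own signal. No fold is given where both groups were below detection.

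A set of 34 gene lists was fixed for cell types, signalling pathways, gene families and stress responses, and the 32 with at least 5 measured members were tested with camera, at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists. Each call was tested again with an estimated correlation, and with fry, whose results are given as counts only. The median of a list is given a second time, where it differed, with undetected members at their bound. The lists, the design and all but 2 alternatives were chosen before the data were examined, as was the rule for the genes named. By that rule 17 genes of Notch signalling, the sort markers and blood and vessel regulators are always given, of which 15 passed the filter. Each induction comparison and the average name the 10 largest rises and the 10 largest falls among called genes with 1 sign in all 3 same-numbered differences. The comparisons of fractions name 6 in each direction, and the interaction names the 10 smallest p-values. Clone and locus names were counted but passed over. Some genes that this rule takes are not reported here. Of a list, 2 to 4 called members with the largest change are named, or failing these the 2 with the highest mean signal.

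The labels give the same replicate numbers to every group, so it was checked whether the numbers pair the arrays. The deviations from the group means correlated at 0.293 to 0.777 over the 84 pairs of arrays with the same number and at -0.626 to 0.0947 over the 168 pairs with different numbers. All 84 lay above the bound of 0.1, and each of the 24 arrays correlated best with its own number. The numbers therefore pair the arrays, and results of a fit with the replicate set as a block, with 14 residual degrees of freedom, are given wherever they changed a call or moved a count by over 1.5 times. A replicate set here is a batch that holds all 8 groups, and values within sets are given as set 1, set 2 and set 3.

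The fits were tested on simulated data for induction in DN over 9591 genes. Without the block, 1 of 66 genes changed by 1.5-fold, 36 of 67 by 2-fold and 56 of 65 by 4-fold were recovered. Of 9376 unchanged genes 0 were called. With the block these were 23 of 66, 61 of 67 and 62 of 65, with 9 of 9376 unchanged genes called. The interaction test called 51 of the 65 genes changed by 4-fold in DN alone, and 60 with the block. Of 32 lists, camera called the 1 shifted in DN and 0 in VE sp, where 0 of 9591 unchanged genes were called. This left real gene correlation untested, and with it estimated 4 of 41 induction list calls passed. Swaps of real arrays gave a median of 19 list calls but can keep real changes, so false ones are neither counted nor excluded.

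The alternatives covered the background correction, the normalization between arrays, the filter, the choice of probe, the block, array weights, the moderation of the variance, the thresholds, the authors' processed table and the omission of each array and each replicate set. A further 2 omissions were added after seeing the data, of the dim arrays (the induced arrays of replicate 2 and the non-induced VE sp array of replicate 3) and of the low-weight arrays (non-induced VE sp and induced DP of replicate 3). Other processing stands for every choice but median scaling, these omissions, the thresholds and the use of fewer arrays. Summaries and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.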

Results

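Messenger RNA was profiled on 24 arrays from day 6 mouse embryoid bodies, with ICN1 induced from day 3 to day 5 or not. Cells of each condition were sorted into the 4 fractions, with 3 replicates each. The induced arrays of replicate 2 were dimmer than their non-induced counterparts, with mean raw intensities of 198 to 314 against 425 to 474. In replicate 3 these were 303 to 454 against 165 to 393, and in replicate 1 471 to 656 against 508 to 596. Levels below are mean log2 intensities ± SD (n = 3), and changes are log2 differences ± SE with limma's adjusted p.

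The genes that encode CD41 and VE-cadherin differed in level among the non-induced fractions. Itga2b, which encodes the integrin subunit CD41, had a level of 11 ± 0.32 in CD41 sp, 11.27 ± 0.21 in DP, 9.52 ± 0.41 in VE sp and 7.91 ± 0.14 in DN. Cdh5, which encodes VE-cadherin, was at 10.36 ± 0.62 in VE sp and 9.64 ± 0.34 in DP, and was not detected on any array of CD41 sp or DN. Notch1 was at 10.24 ± 0.61 in VE sp, 9.05 ± 0.24 in DP, 6.94 ± 0.45 in DN and 5.40 ± 0.55 in CD41 sp. Whether its probe also reads the ICN1 transgene is not given in the sources used here. Kdr, the VEGF receptor that marks early mesoderm and endothelium, did not pass the filter. Its probe was detected on 1 induced VE sp array, so Kdr was not measured here.

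**Figure D1:**
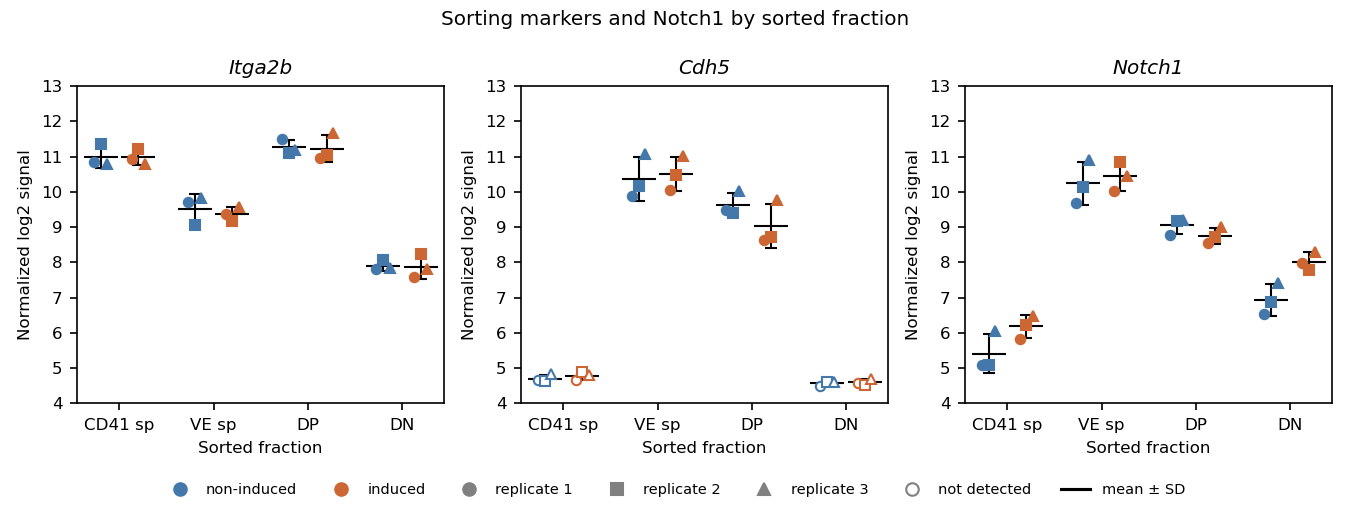
Normalized log2 intensity (vertical axis) of Notch1 and of the genes encoding the sort markers CD41 and VE-cadherin in the 4 fractions, non-induced and induced; points are the 3 arrays of a group, open where the probe was not detected, and bars give the mean ± SD. Cdh5 stood at 10.36 in non-induced VE sp and 9.64 in DP and was not detected in CD41 sp or DN.

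Non-induced CD41 sp cells differed from DN cells by a platelet and blood progenitor profile. Cxcl4, the platelet chemokine PF4, was at least 107-fold higher, and Treml1, a platelet granule receptor, at least 47.7-fold. The platelet glycoprotein Gp5 was higher by 5.89 ± 0.51, with detection on 2 of 3 DN arrays, the platelet kinase substrate Plek by 5.61 ± 0.59 and the blood cell adaptor Sla by 6.00 ± 0.37 (other probes 2.34 and 3.04). The hormone precursor Trh (-4.75 ± 0.45), the pluripotency-associated Dppa5 (-4.64 ± 0.52), the thyroxine carrier Ttr (-4.39 ± 0.49), Phlda2 (-4.33 ± 0.48) and the epithelial keratins Krt1-18 (-4.31 ± 0.36) and Krt2-8 (-4.25 ± 0.39) were lower. Itga2b was higher by 3.09 ± 0.24 (adjusted p = 6.45e-09), whereas Notch1 was lower by a log2 change of -1.54 ± 0.32 (0.00123) and the Notch target Hes1 by -1.77 ± 0.39 (0.00216). In all, 671 genes were higher and 827 lower, 1498 together, of which 241 carried clone names, and 2903 were called with the replicate set as a block (1433 higher, 1470 lower). The block added calls for Hey1 (-1.33 ± 0.61, adjusted p = 0.172 without and 0.00219 with it), the blood regulators Runx1 (1.56 ± 0.57, 0.0718 and 0.000932), Gata1 (0.67 ± 0.29, 0.142 and 0.0293) and Tal1 (0.89 ± 0.31, 0.0564 and 0.000656), and the mesodermal Foxc2 (at least 1.20-fold lower, 0.120 and 0.0265). Foxc2 was also called without non-induced DN array 2 (0.0213). Under median scaling Hes1 was lost, as were Mscp, Nfe2 and Gfi1b below (0.0831 to 0.246).

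Of 20 measured megakaryocyte and platelet genes, 18 were higher in CD41 sp than in DN and 0 lower, 19 and 0 adjusted over the list alone. Their median was 3.22 and the set means were 3.56, 3.96 and 3.16 (adjusted p = 4.18e-26). Blood progenitor genes were higher as a group, with 12 of 24 higher and 1 lower, 15 and 1 adjusted over the list alone. Their median was 0.94, or 0.88 with undetected members at their bound, and their set means 1.22, 1.44 and 1.08 (3.17e-09), led by the signalling and cytoskeletal regulators Vav1 (3.83 ± 0.38, detected on 2 of 3 DN arrays) and Was (3.68 ± 0.44) and the homeobox gene Meis1 (2.69 ± 0.34). Among 16 myeloid genes 7 were higher and 0 lower, 10 and 0 adjusted over the list alone, including Coro1a (3.80 ± 0.25, other probes 2.71, 2.19 and 3.09), Laptm5 (3.63 ± 0.22) and the granule enzyme Mpo (2.97 ± 0.36, detected on 1 of 3 DN arrays, other probes 0.79, not called, and 1.09). Their median was 0.63, or 0.31 with undetected members at their bound, and the set means were 1.30, 1.08 and 1.24 (adjusted p = 1.05e-07). The lower groups were mesenchyme and matrix genes, with 0 of 21 higher and 16 lower, 0 and 17 adjusted over the list alone, among them the basement membrane collagens Col4a2 (-3.71 ± 0.33) and Col4a1 (-3.49 ± 0.35), the fibulin Fbln1 (-3.39 ± 0.29, other probes -0.43, not called, and -1.13) and the growth factor receptor Pdgfra, at least 6.31-fold lower. Their median was -1.53, or -1.10 with undetected members at their bound, and the set means were -1.43, -1.61 and -1.45 (adjusted p = 2.89e-14). Primitive streak genes were lower with 8 of 10 members, 9 adjusted over the list alone, including Cdx2 (-3.80 ± 0.25, detected on 2 of 3 CD41 sp arrays) and T, at least 5.98-fold lower. Their median was -2.04, or -1.50 with undetected members at their bound, and the set means were -2.27, -1.85 and -1.95 (adjusted p = 4.13e-13). Endoderm genes were lower with 9 of 13 members, as many adjusted over the list alone, including Spink3 (-4.05 ± 0.71), Dab2 (-3.30 ± 0.49, detected on 2 of 3 CD41 sp arrays) and Gata6 (-2.92 ± 0.28). Their median was -1.68, or -1.45 with undetected members at their bound, and the set means were -1.71, -1.66 and -2.21 (adjusted p = 3.17e-09). So were epithelial genes with 9 of 13, 11 adjusted over the list alone, including the junction protein Cldn6 (-4.24 ± 0.45, detected on 2 of 3 CD41 sp arrays). Their median was -3.00, or -2.50 with undetected members at their bound, and the set means were -2.38, -2.20 and -2.59 (adjusted p = 2.89e-14). These 7 groups passed with an estimated correlation too, at adjusted p between 0.00014 and 0.00794. Erythroid genes did not pass (0.820), with 3 of 32 higher and 2 lower, 3 and 3 adjusted over the list alone. Their mean of 0.03 and the direction of the test were positive and their median of -0.02 negative, the set means were 0.19, -0.33 and 0.22, and the transporter Mscp (-1.44 ± 0.38) and the regulators Nfe2 (1.19 ± 0.29) and Gfi1b (0.99 ± 0.27) went both ways. The Mscp call was lost without array 2 of either fraction (0.0828 and 0.0854) and that of Gfi1b without CD41 sp array 2 or DN array 1 or 2 (0.0527 to 0.0931).

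Set against DN, VE sp cells carried an endothelial profile. The endothelial junction proteins Cldn5 and Esam1 were higher by 7.57 ± 0.42 and 7.52 ± 0.38, the vascular transcription factor Sox18 by 6.58 ± 0.27, the surface receptor C1qr1 (CD93) by 6.31 ± 0.41 and the adhesion molecule Icam2 by 6.28 ± 0.45, and the vascular regulator Rasip1 was at least 76.3-fold higher. On DN arrays, Cldn5, C1qr1 and Icam2 were detected on 1 of 3 and Sox18 on 2 of 3. The red cell genes Eraf (-5.78 ± 0.49), Hbb-y (-5.65 ± 0.58), Trim10 (-5.63 ± 0.31, detected on 2 of 3 VE sp arrays), Slc4a1 (-5.20 ± 0.74) and Alas2 (-5.03 ± 0.35) were lower. Cdh5 was at least 42.9-fold higher, Notch1 higher by 3.30 ± 0.32 (adjusted p = 6.22e-08), and the Notch targets Hey1 by 2.51 ± 0.61 (0.00379), Hey2 by 1.68 ± 0.32 and Nrarp by 2.43 ± 0.34. Etsrp71 (Etv2), a regulator of endothelial specification, was higher by 1.89 ± 0.35, Foxc2 by 1.84 ± 0.37 and Itga2b by 1.62 ± 0.24, and Gata1, the erythroid regulator, was lower (-3.34 ± 0.29, other probe -1.84). Gata2 was higher by 1.10 ± 0.30 (0.00831), a call lost without non-induced VE sp array 1 (0.0674) or DN array 2 (0.0517), and under median scaling Gata2 and Hey1 were lost (0.449 and 0.0913). There were 1191 higher and 1170 lower genes, 2361 in all with 427 clone names, and 4205 with the block (1897 higher, 2308 lower). Under median scaling in place of quantile normalization the median of all genes was -0.26 instead of -0.09.

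Endothelial genes were higher in VE sp with 31 of 32 members, as many adjusted over the list alone. Their median was 4.68 and the set means were 4.41, 5.03 and 4.65 (adjusted p = 1.21e-47). Of 22 Notch pathway components 8 were higher and 0 lower, 10 and 0 adjusted over the list alone, among them the glycosyltransferase Mfng, at least 36.3-fold higher (other probe 1.83), and the receptor Notch4 (4.77 ± 0.29, other probe 1.25). Their median was 0.48, or 0.33 with undetected members at their bound, and the set means were 0.84, 1.09 and 0.85 (adjusted p = 0.000124). Arterial genes included the gap junction protein Gja4 (6.08 ± 0.38), the transcription factor Sox17 (4.39 ± 0.36) and the chemokine Cxcl12 (-2.83 ± 0.30, other probe -0.41, not called), the first 2 detected on 2 of 3 DN arrays and Cxcl12 on 2 of 3 VE sp arrays, with 13 of 19 higher and 1 lower, as many adjusted over the list alone. Their median was 1.42, or 1.40 with undetected members at their bound, and the set means were 1.52, 2.04 and 1.39 (adjusted p = 7.23e-08). Erythroid genes were lower with 28 of 32, as many adjusted over the list alone. Their median was -3.05, or -2.81 with undetected members at their bound, and the set means were -2.99, -3.59 and -2.95 (adjusted p = 1.11e-26). Epithelial genes were lower too, with 2 of 13 higher and 10 lower, 2 and 11 adjusted over the list alone, Cldn6 at -4.66 ± 0.45, detected on 2 of 3 VE sp arrays, and Krt1-18 at -4.22 ± 0.36. Their median was -2.54 and the set means were -2.16, -1.89 and -2.29 (adjusted p = 5.41e-08). Smooth muscle and pericyte genes were lower with 1 of 12 higher and 9 lower, the same when adjusted over the list alone. Their median was -1.13, or -0.93 with undetected members at their bound, and the set means were -0.93, -0.96 and -0.91 (adjusted p = 0.000374). They included the contractile proteins Acta2 (-3.74 ± 0.38) and Tpm2 (-1.92 ± 0.25, detected on 2 of 3 VE sp arrays), with the myosin kinase Mylk at least 2.93-fold higher. With an estimated correlation all 6 calls held at adjusted p between 8.97e-05 and 0.0191, but with the estimate and the block together the arterial and the smooth muscle calls were lost (adjusted p = 0.0528 for both).

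DP cells, set against DN, combined endothelial and blood genes. Esam1 was higher by 6.54 ± 0.38, Sox18 by 6.37 ± 0.27, Gja4 by 6.14 ± 0.38, the leukotriene pathway protein Alox5ap by 6.22 ± 0.37, the thrombin receptor F2rl3 by 5.86 ± 0.36 and Sla by 5.61 ± 0.37 (other probes 2.00 and 2.88), with Sox18 and Gja4 detected on 2 of 3 DN arrays. Phlda2 (-5.74 ± 0.48), Slc4a1 (-5.60 ± 0.74), Trh (-5.33 ± 0.45), Acta2 (-5.33 ± 0.38), Dppa5 (-5.31 ± 0.52) and Krt1-18 (-5.10 ± 0.36) were lower, and of these Phlda2 and Slc4a1 were detected on 2 of 3 DP arrays and Trh and Krt1-18 on 1. Itga2b was higher by 3.36 ± 0.24, Cdh5 at least 25.9-fold, Notch1 by 2.11 ± 0.32, Nrarp by 1.98 ± 0.34 and Etsrp71 by 2.12 ± 0.35, and Gata1 was lower (-1.82 ± 0.29, other probe -1.20). Runx1, required for blood formation from endothelium, was higher by 1.74 ± 0.57 (adjusted p = 0.0321), a call kept only when non-induced DP array 3 was the one left out and lost without any of the other 5 arrays (0.0522 to 0.149), under median scaling (0.0651) and without filter (0.0806). The comparison called 1066 higher and 1048 lower genes, 2114 in all with 360 clone names, against 3779 with the block (1813 higher, 1966 lower).

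All 32 endothelial genes were higher, as many adjusted over the list alone. Their median was 3.51, or 3.19 with undetected members at their bound, and the set means were 3.68, 3.48 and 3.22 (adjusted p = 1.05e-37). Blood progenitor genes were higher with 15 of 24 and 1 lower, 17 and 1 adjusted over the list alone, including the surface sialomucin Cd34, at least 19.9-fold, and Was (3.78 ± 0.44). Their median was 1.42 and the set means were 1.54, 1.62 and 1.32 (adjusted p = 1.52e-09). Of 16 myeloid genes 11 were higher, as many adjusted over the list alone, including Lyz, at least 33.5-fold, and Mpo (4.67 ± 0.36, detected on 1 of 3 DN arrays, other probes 2.16 and 2.69). Their median was 2.14, or 1.76 with undetected members at their bound, and the set means were 2.09, 1.99 and 2.17 (adjusted p = 2.06e-11). Megakaryocyte and platelet genes were higher with 13 of 20 and 1 lower, 14 and 1 adjusted over the list alone, including Plek (5.01 ± 0.59) and Cxcl4, at least 21.7-fold. Their median was 2.04 and the set means were 2.07, 2.52 and 1.94 (adjusted p = 3.04e-10). This last call was lost (adjusted p = 0.0533 with an estimated correlation). Erythroid genes, Eraf among them (-5.07 ± 0.49), were lower with 26 of 32, as many adjusted over the list alone. Their median was -2.36, or -2.35 with undetected members at their bound, and the set means were -2.26, -2.78 and -2.41 (adjusted p = 2.25e-19). So were epithelial genes with 10 of 13, 11 adjusted over the list alone, Krt2-8 among them (-5.08 ± 0.39). Their median was -2.89, or -2.58 with undetected members at their bound, and the set means were -2.43, -2.39 and -2.91 (adjusted p = 8.58e-12). The other 5 calls held with an estimated correlation at adjusted p between 0.000186 and 0.00345.

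DP cells differed from VE sp cells by higher blood genes and lower arterial genes. The chemokine Ccl3 was higher by 5.38 ± 0.33, Sla by 5.19 ± 0.37 (other probes 2.20 and 2.64), the transporter Slco4a1 by 4.76 ± 0.44 (other probe 0.33, not called), Cxcl4 by 4.05 ± 0.69, Gp5 by 3.83 ± 0.51 and the coagulation factor F13a1 by 3.78 ± 0.28. Ccl3 and Gp5 were detected on 1 of 3 VE sp arrays, and Sla, Slco4a1 and Cxcl4 on 2. The sialyltransferase St6gal1 (-3.94 ± 0.34), Gap43 (-3.83 ± 0.50), the probe annotated Tcf3 (-3.69 ± 0.38, other probe -0.72), the endothelial sialomucin Emcn (-3.68 ± 0.50), the endocytic adaptor Dab2 (-3.63 ± 0.49) and Nos3, the endothelial nitric oxide synthase (-3.49 ± 0.38), were lower, with St6gal1 and Dab2 detected on 2 of 3 DP arrays. Runx1 was higher by 2.45 ± 0.57 (adjusted p = 0.00592, lost without non-induced VE sp array 3 at 0.0529), with detection on 2 of 3 VE sp arrays, Itga2b by 1.74 ± 0.24 and Gata1 by 1.52 ± 0.29 (other probe 0.65, not called). Hey1 (-3.27 ± 0.61) and Hey2 (-1.94 ± 0.32) were lower, Foxc2 was at least 4.53-fold lower, and Notch1 was lower by a log2 change of -1.19 ± 0.32 (0.0154), a call lost without non-induced VE sp array 3 (0.124), DP array 1 (0.0778) or the dim or low-weight arrays (0.153 and 0.116) and under median scaling (0.234). Calls gained with the block were Cdh5 (-0.73 ± 0.30, adjusted p = 0.159 without and 0.0153 with it), Hes1 (-0.81 ± 0.39, 0.260 and 0.0295), Gata2 (-0.91 ± 0.30, 0.0550 and 0.0183) and Tal1 (0.71 ± 0.31, 0.190 and 0.00619), and Gata2 was also called without non-induced VE sp array 3 (0.0279) or DP array 1 (0.0248). In all, 372 genes were higher and 605 lower, 977 together with 153 clone names, and 2062 with the block (965 higher, 1097 lower). Median scaling gave a median of all genes of 0.30 instead of 0.05 and 229 higher and 168 lower genes, a share of 57.7% higher against 38.1%.

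Megakaryocyte and platelet genes were higher in DP than in VE sp with 13 of 20, 17 adjusted over the list alone. Their median was 1.66 and the set means were 1.85, 2.59 and 1.82 (adjusted p = 2.37e-19). Myeloid genes were higher with 9 of 16 and 1 lower, 10 and 1 adjusted over the list alone, from Lyz (3.74 ± 0.28) and Coro1a (3.20 ± 0.25, other probes 2.40, 2.04 and 2.72) to the macrophage receptor Mrc1 (-3.03 ± 0.30). Their median was 1.16, or 1.13 with undetected members at their bound, and the set means were 1.26, 1.10 and 1.19 (adjusted p = 2.31e-09). Blood progenitor genes were higher with 11 of 24 and 2 lower, 14 and 3 adjusted over the list alone, including Vav1 (2.89 ± 0.38), Was (2.33 ± 0.44) and Gfi1b (2.12 ± 0.27). Their median was 0.82 and the set means were 0.79, 0.90 and 0.90 (adjusted p = 3.97e-07). Endothelial genes were lower with 1 of 32 higher and 16 lower, 1 and 22 adjusted over the list alone, including Cldn5 (-3.30 ± 0.42) and Sox17 (-3.08 ± 0.36). Their median was -0.97 and the set means were -0.73, -1.55 and -1.43 (adjusted p = 5.66e-14). Arterial genes were lower with 13 of 19, as many adjusted over the list alone. Their median was -1.27 and the set means were -1.27, -1.68 and -1.50 (adjusted p = 1.99e-14). Of 17 Hox genes, which pattern the body axis, 13 were lower, 14 adjusted over the list alone, including Hoxb7 (-3.00 ± 0.33, detected on 2 of 3 DP arrays) and Hoxb6 (-2.62 ± 0.29). Their median was -1.19 and the set means were -1.06, -1.42 and -1.31 (adjusted p = 7.01e-14). All 6 calls held with an estimated correlation, at adjusted p between 0.00118 and 0.00804, the endothelial one not with the estimate and the block together (0.0544).

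CD41 sp cells had more red cell and fewer endothelial transcripts than DP cells. The globins Hbb-y, Hba-x and Hba-a1 were higher by 4.89 ± 0.58, 4.14 ± 0.50 and 4.09 ± 0.46, the globin chaperone Eraf by 4.87 ± 0.49, and the anion exchanger Slc4a1 by 4.46 ± 0.74, with detection on 2 of 3 DP arrays. Xlkd1 (LYVE1), a hyaluronan receptor of some endothelia, was at least 24.6-fold lower, Cdh5 at least 24.2-fold and Cldn5 at least 18.0-fold. Rasgrp3 (-4.82 ± 0.44, detected on 2 of 3 CD41 sp arrays), Col4a2 (-4.74 ± 0.33) and Sox18 (-4.58 ± 0.27) were lower too. Gata1 was higher by 2.49 ± 0.29, and Notch1 (-3.64 ± 0.32), Nrarp (-1.97 ± 0.34) and Etsrp71 (-1.82 ± 0.35) were lower. Hes1 was lower (-1.22 ± 0.39, adjusted p = 0.0424), a call lost without any 1 of the 6 arrays (0.0568 to 0.195), under median scaling (0.316) and under other processing (0.0945 to 0.127), and Itga2b did not differ detectably (-0.27 ± 0.24, 0.605). Tal1 was called only with the block (0.60 ± 0.31, adjusted p = 0.272 without and 0.0173 with it). There were 502 higher and 681 lower genes, 1183 in all with 204 clone names, and 2569 with the block (1300 higher, 1269 lower). Erythroid genes were higher with 29 of 32, 31 adjusted over the list alone. Their median was 2.20, or 2.06 with undetected members at their bound, and the set means were 2.45, 2.45 and 2.63 (adjusted p = 1.54e-35). Endothelial genes were lower with 29 of 32, 30 lower and 1 higher adjusted over the list alone. Their median was -3.10, or -2.97 with undetected members at their bound, and the set means were -3.30, -2.88 and -2.67 (adjusted p = 1.10e-48). Both held with an estimated correlation (adjusted p = 0.000568 and 7.83e-05). Myeloid genes were lower with 6 of 16, as many adjusted over the list alone, including Lyz (-3.08 ± 0.28), Mrc1 (-2.39 ± 0.30) and Lyzs (-2.38 ± 0.25), the last 2 detected on 1 and 2 of 3 CD41 sp arrays. Their median was -0.42 and the set means were -0.79, -0.91 and -0.93 (adjusted p = 0.000205, and 0.0426 with an estimated correlation). Megakaryocyte and platelet genes were higher with 12 of 20, 13 adjusted over the list alone, including Gp1bb (3.77 ± 0.34, detected on 2 of 3 DP arrays) and Treml1 (2.66 ± 0.31), but that call was lost (adjusted p = 0.0973 with an estimated correlation). Their median was 1.36 and the set means were 1.49, 1.44 and 1.22 (adjusted p = 6.77e-09).

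After ICN1 induction in CD41 sp, the mast cell protease genes Mcpt1 and Mcpt4 rose at least 8.86-fold (adjusted p = 1.11e-10) and at least 4.51-fold (0.000604). Mcpt1 had been undetected on every non-induced array and reached 8.19 ± 0.28. The aldehyde dehydrogenase Aldh1b1 rose at least 3.66-fold (0.00309), the sulfotransferase Chst2 at least 2.65-fold and Nrarp, a feedback inhibitor and target of Notch, by 2.23 ± 0.34 (both 0.00286). Maged2 rose by 1.52 ± 0.24 (0.0035, lost without non-induced array 1 at 0.0519). Rgs1, a brake on G protein signalling, fell by 1.13 ± 0.15 (0.00105, other probes -0.81 and -1.01, not called), and the platelet chemokine Ppbp fell by 1.34 ± 0.23 (0.0120, other probe -1.27, not called), with detection on 2 of 3 induced arrays. The Ppbp call was lost without non-induced array 1 or 2 or induced array 1 or 3 (0.0910 to 0.160). In all 7 genes rose and 2 fell, 1 with a clone name, and with the block 41 rose and 46 fell. Hey1 (2.60 ± 0.61, adjusted p = 0.133 without and 7.98e-05 with the block), Hes1 (1.69 ± 0.39, 0.124 and 0.00143) and Etsrp71 (-1.06 ± 0.35, 0.598 and 0.0195) were called with it alone. Notch1 (0.78 ± 0.32, 0.959), Dtx1 (at least 1.78-fold higher, 0.452), Runx1 (0.42), Gata1 (-0.14), Gata2 (0.08), Tal1 (-0.03) and Itga2b (-0.02) were not called, and Cdh5, Heyl and Foxc2 were undetected in both conditions. Median scaling gave a median of all genes of -0.19 instead of -0.01 and 2 rises and 1 fall, ending the calls of Aldh1b1, Chst2, Maged2, Nrarp and Ppbp (0.149 to 1.00). Aldh1b1, Chst2 and Ppbp were lost also under other processing (0.0510 to 0.0852).

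Notch target genes rose in CD41 sp as a group, although 1 of 14 members passed over all genes and 5 adjusted over the list alone. Their mean was 0.71 and their median 0.25, or 0.23 with undetected members at their bound, and the set means were 0.77, 0.58 and 0.79 (adjusted p = 2.28e-09). Targets of p53, the DNA damage regulator, fell as a group with 0 of 16 members called by limma, 7 at an unadjusted p under 0.05 and 6 adjusted over the list alone, for example Ccng1 (-0.69 ± 0.17, adjusted p = 0.176 without and 0.0336 with the block) and Mdm2 (-0.30 ± 0.26). Their median was -0.57 and the set means were -0.53, -0.55 and -0.28 (adjusted p = 2.08e-07). Both calls held with an estimated correlation (adjusted p = 0.00276 and 0.0147). Integrated stress response genes rose with 0 of 23 members called, 3 at an unadjusted p under 0.05 and 1 adjusted over the list alone, such as Asns (0.47 ± 0.19) and Gars (0.33 ± 0.24), but this call was lost (adjusted p = 0.0553 with an estimated correlation). Their median was 0.33 and the set means were 0.45, 0.23 and 0.42 (adjusted p = 5.15e-06). Megakaryocyte and platelet genes fell with 1 of 20 called, as many adjusted over the list alone, with Nfe2 at -0.12 ± 0.29. Their median was -0.23 and the set means were -0.52, -0.11 and -0.20 (adjusted p = 0.0199, but adjusted p = 0.603 with an estimated correlation). That call was lost without non-induced array 2 (0.936), induced array 1 (0.421) or induced array 3 (0.595).

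**Figure D2:**
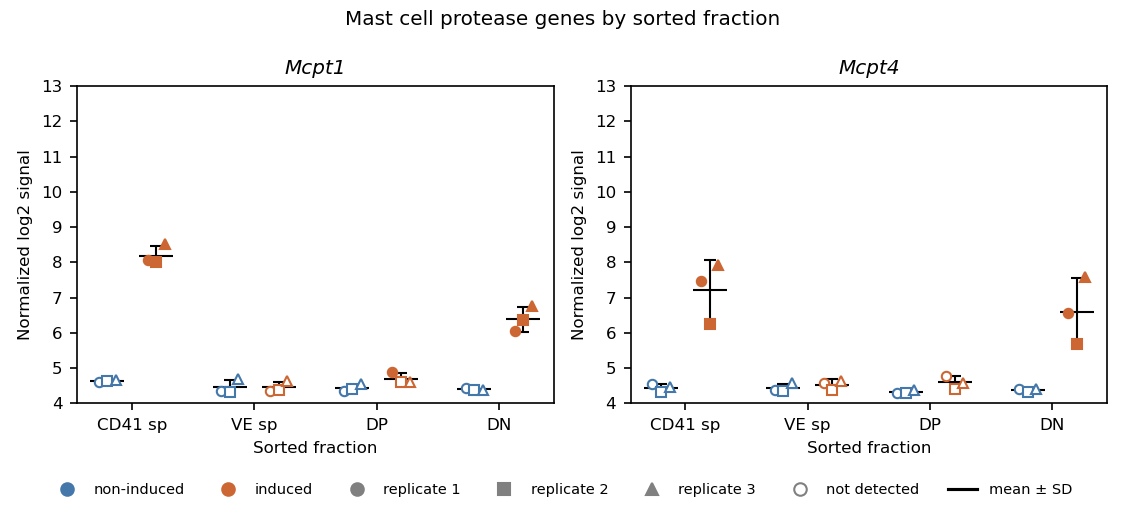
Normalized log2 intensity (vertical axis) of Mcpt1 and Mcpt4 in the 4 fractions, non-induced and induced; points are the 3 arrays of a group, open where the probe was not detected, and bars give the mean ± SD. Mcpt1 reached 8.19 in induced CD41 sp and 6.39 in induced DN and was undetected on all non-induced arrays.

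In VE sp, 94 genes rose and 15 fell after induction. Vwf, the endothelial clotting protein, rose by 3.02 ± 0.55 (adjusted p = 0.00497), the collagen gene Emid2 by 3.85 ± 0.53 (0.00044) and Col5a1, a fibrillar collagen chain, by 2.19 ± 0.35 (0.00169). The natriuretic peptide receptor Npr3 rose by 2.84 ± 0.31 (2.52e-05) and Corin, the protease that activates that peptide, at least 4.34-fold (2.29e-05). Igfbp5 rose by 2.84 ± 0.51, the adaptor Grb7 by 2.48 ± 0.36, the homeobox gene Irx5 by 2.46 ± 0.44, the protein kinase C gene Prkcb by 2.43 ± 0.19 (2.14e-07) and Ccdc3 by 2.24 ± 0.40. Vwf, Irx5 and Prkcb were detected on 2 of 3 non-induced arrays and Ccdc3 on 1. The largest falls were Pde4dip (-2.36 ± 0.38), Oit3 (-1.81 ± 0.34, lost without induced array 1 at 0.0558), Hoxb6 (-1.74 ± 0.29), Nrip3 (-1.71), the glypican Gpc3 (-1.42 ± 0.24, other probe -1.35, not called), the vascular collagen Col15a1 (-1.36 ± 0.21) and the apelin receptor gene Agtrl1 (-1.30 ± 0.32, 0.0472), with Pde4dip and Col15a1 detected on 2 of 3 induced arrays. The kinase Pim3 (-1.25), the lipid transfer protein Pltp (-1.19, other probe -0.25, not called) and the kinase Dyrk3 (-1.08) fell as well. Agtrl1 and Pltp lost their call whichever of the 6 arrays was left out, Nrip3 for all but non-induced array 3, Pim3 for all but induced array 2 and Dyrk3 for all but non-induced array 3 and induced array 1, at adjusted p between 0.0561 and 0.328.

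Foxc2, which acts with Notch in arterial development, rose in VE sp by 1.72 ± 0.37 (adjusted p = 0.0170), a call kept only when the array left out was non-induced array 3 (otherwise 0.0538 to 0.103). Hey1 (1.77 ± 0.61, 0.298 without and 0.00154 with the block) and Dtx1 (1.17 ± 0.39, 0.248 and 0.0291) were called only with the block. Notch1 (0.20), Nrarp (0.45), Hes1 (0.02), Hey2 (0.05), Cdh5 (0.14), Itga2b (-0.15), Runx1 (-0.75), Gata1 (at least 1.09-fold lower), Gata2 (0.40), Tal1 (-0.01) and Etsrp71 (-0.33) were not called. The 109 calls included 19 clone names, and with the block 303 genes rose and 115 fell. Without non-induced array 1 or induced array 1 there were 70, and without induced array 3 there were 65. Median scaling gave a median of all genes of 0.14 instead of 0.01 and 23 rises and 0 falls, and Igfbp5, Irx5, Foxc2, 1810057C19Rik, Nedd9, Rgs5 and all 10 falls named lost their calls (0.0642 to 1.00). Without the dim arrays Irx5, Agtrl1, Pltp, Col6a1 and Rgs5 were lost (0.0834 to 0.212), without the low-weight arrays Agtrl1 and Pltp (0.0553 and 0.0635). Under other processing the lost calls were Nrip3, Agtrl1, Pim3, Pltp, Dyrk3, Col6a1 and Rgs5 (0.0507 to 0.280). Arterial genes rose, 2 of 19 over all genes and 6 adjusted over the list alone, including the clone-named 1810057C19Rik (2.69 ± 0.51, lost without non-induced array 2 or induced array 3 at 0.0538 and 0.0559). Their median was 0.51 and the set means were 0.72, 0.50 and 0.81 (adjusted p = 4.02e-08, but adjusted p = 0.0850 with an estimated correlation). Notch targets rose with 1 of 14, 3 adjusted over the list alone. Their mean was 0.42 and their median 0.37, or 0.24 with undetected members at their bound, and the set means were 0.48, 0.25 and 0.53 (adjusted p = 0.0114, lost without induced array 1 at 0.0739, and adjusted p = 0.153 with an estimated correlation). Targets of the growth factor BMP rose with 1 of 10 higher and 0 lower, 5 and 2 adjusted over the list alone, with Idb1 at 0.97 ± 0.41 (adjusted p = 0.552 without and 0.0305 with the block) and Bmp4 at -0.97 ± 0.34 (0.339 and 0.0103). Their median was 0.74 and the set means were 0.31, 0.51 and 0.58 (adjusted p = 0.0154, but adjusted p = 0.285 with an estimated correlation). The BMP call was lost without non-induced array 2 or 3 or induced array 1 (0.0745 to 0.106), under median scaling (0.141) and without the dim or the low-weight arrays (0.104 and 0.0870). Hox genes fell, 1 of 17 and 6 adjusted over the list alone, with Hoxb5 at -0.95 ± 0.35 and Hoxb2 at -0.22 ± 0.48. Their median was -0.26, or -0.22 with undetected members at their bound, and the set means were -0.26, -0.35 and -0.50 (adjusted p = 2.03e-05, but adjusted p = 0.153 with an estimated correlation). Integrated stress response genes fell with 0 of 23 called, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone, with Asns at -0.51 ± 0.19 and Gars at -0.24 ± 0.24. Their median was -0.29, or -0.24 with undetected members at their bound, and the set means were -0.43, -0.39 and -0.13 (adjusted p = 0.00149, but adjusted p = 0.153 with an estimated correlation). Immediate early genes, which respond within minutes to stimuli, fell with 0 of 13 members called, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Egr1 at 0.87 ± 0.56 and Dusp1 at -0.37 ± 0.40. Their median was -0.89 and the set means were -1.69, -0.99 and -0.14 (adjusted p = 2.96e-05, but adjusted p = 0.193 with an estimated correlation). Other calls ended were those of the stress response genes without the dim arrays (0.141) and the Notch targets under other processing (0.124).

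In DP, 8 genes rose and 5 fell after induction. Col5a1 rose by 2.22 ± 0.35 (adjusted p = 0.00817), Chst2 by 1.61 ± 0.24 (0.00701), the fat cell regulator Pparg by 1.45 ± 0.23 (0.00817), the integrin subunit Itga9 by 1.37 ± 0.17 (0.00118), the metalloproteinase inhibitor Timp2 by 1.26 ± 0.23 (0.0264), the tetraspanin Cd53 by 0.93 ± 0.16 (0.0110) and Csh2 by 0.93 ± 0.18 (0.0308), and Ggtla1 rose at least 1.30-fold (0.0264). Oit3 fell by 2.08 ± 0.34 (0.0086) and Egfl7, a secreted endothelial protein, by a log2 change of -0.88 ± 0.17 (0.0302, other probes -0.99 and -0.21, not called). Pparg was detected on 2 of 3 and Cd53 on 1 of 3 non-induced arrays. Of these calls that of Itga9 was kept without any 1 array, Chst2 was lost without induced array 3 (0.0509), and Egfl7 was lost without each of the 6 (0.0654 to 0.181). Other calls were lost, Csh2 without all but induced array 1 (0.0592 to 0.181), Ggtla1 without all but non-induced array 1 (0.0666 to 0.181), Col5a1 without non-induced 1 or 3 or induced 2 or 3 (0.0514 to 0.0592), Cd53 without non-induced 3 or any induced array (0.0523 to 0.0998), Timp2 without non-induced 1 or 2 or induced 1 or 3 (0.0547 to 0.181), Oit3 without non-induced 2 or induced 1 or 3 (0.0609 to 0.0895) and Pparg without non-induced 1 or induced 2 or 3 (0.0511 to 0.0733). Of the 13 called genes 3 had clone names, and with the block 99 genes rose and 56 fell. The count was 7, 6 and 6 without non-induced array 1, 2 and 3, and 6, 8 and 2 without induced array 1, 2 and 3. Median scaling kept only Col5a1, Pparg and Oit3 (others 0.798 to 1.00). Without the dim arrays Col5a1, Csh2, Egfl7 and Ggtla1 were lost (0.0828 to 0.143), without the low-weight arrays these and Oit3 and Timp2 (0.0537 to 0.136). Other processing ended Cd53, Csh2, Egfl7 and Ggtla1 (0.0507 to 0.199). Hey1 (2.87 ± 0.61, adjusted p = 0.0689 without and 3.91e-05 with the block) and Etsrp71 (-1.34 ± 0.35, 0.197 and 0.00236) were called with the block, and Hey1 also without non-induced array 1 (0.0462). Not called were Notch1 (-0.30), Cdh5 (-0.60), Itga2b (-0.05), Nrarp (0.10), Hes1 (0.27), Dtx1 (0.83), Gata2 (0.84), Runx1 (0.05), Tal1 (0.02), Gata1 (-0.15) and Foxc2, at least 1.61-fold higher (0.653).

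Endothelial genes fell in DP with 1 of 32 called and 5 adjusted over the list alone, with the blood and vessel regulator Lmo2 at -0.44 ± 0.27. Their median was -0.33 and the set means were -0.42, -0.31 and -0.45 (adjusted p = 1.05e-08, but adjusted p = 0.139 with an estimated correlation). Targets of p53 fell with 0 of 16 called, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone, with Ccng1 at -0.37 ± 0.17 and Mdm2 at -0.27 ± 0.26. Their median was -0.34 and the set means were -0.56, -0.32 and -0.33 (adjusted p = 2.41e-06, but adjusted p = 0.0564 with an estimated correlation). Notch targets rose with 0 of 14 called, 5 higher and 1 lower at an unadjusted p under 0.05 and 2 higher and 1 lower adjusted over the list alone. Their mean was 0.43 and their median 0.31 and the set means were 0.47, 0.42 and 0.40 (adjusted p = 0.00748, lost without induced array 1 at 0.0613 and without filter at 0.0680, and adjusted p = 0.195 with an estimated correlation). Immediate early genes fell with 0 of 13 called, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Egr1 at -0.17 ± 0.56 and Dusp1 at -0.88 ± 0.40, a call lost without non-induced array 1 (0.215), induced array 2 (0.442) or the dim arrays (0.401) and without filter (0.0860). Their median was -0.41 and the set means were -0.47, -1.29 and 0.02 (adjusted p = 0.00544, but adjusted p = 0.581 with an estimated correlation).

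In DN, induction raised Notch targets and lowered endoderm genes. Nrarp rose by 2.92 ± 0.34 (adjusted p = 4.31e-05), Hey1 by 2.76 ± 0.61 (0.0265), the Notch pathway ubiquitin ligase Dtx1 by 1.78 ± 0.39 (0.0238) and the Notch target Heyl at least 2.00-fold (6.40e-05). Aldh1b1 rose by 3.04 ± 0.37 (6.08e-05), Emid2 by 2.45 ± 0.53 (0.0225), Rerg by 2.18 ± 0.28, Gja4 by 2.10 ± 0.38, Maged2 by 2.09 ± 0.24 and the collagens Col6a1 and Col5a1 by 1.99 ± 0.21 and 1.99 ± 0.35, and Mcpt4 and Mcpt1 rose at least 3.17-fold (0.00149) and 2.73-fold (6.52e-06). The liver and yolk sac products Ttr (-3.04 ± 0.49, 0.00154), Apoa1 (-1.92 ± 0.27), Apom (-1.79 ± 0.27) and Rbp4 (-1.44 ± 0.20) fell, as did the transcription factors Hlx1 (-1.53 ± 0.23), Hoxc9 (-1.30 ± 0.18) and Mesp1, a marker of early mesoderm (-1.30 ± 0.23), and Dcxr (-1.47 ± 0.32, 0.0218, other probe -1.23, not called), the peptidase Dpp4 (-1.39 ± 0.31, 0.0315) and Agtrl1 (-1.37 ± 0.32, 0.0390). Of the risers Aldh1b1 and Dtx1 were detected on 1 and Gja4 on 2 of 3 non-induced arrays, and of the fallers Hlx1 and Rbp4 were detected on 2 and Mesp1 on 1 of 3 induced arrays. Calls for Hey1 (0.0539 to 0.156) and Dtx1 (0.0529 to 0.122) were kept only when the array left out was induced array 2, that for Dpp4 only when it was non-induced array 2 (0.0524 to 0.236), and that for Dcxr was lost whichever of the 6 was left out (0.0568 to 0.0948). Emid2 was lost without non-induced 2 or 3 or induced 1 or 3 (0.0503 to 0.156) and Agtrl1 without non-induced 1 or 3 or induced 2 or 3 (0.154 to 0.273). In all 70 genes rose and 19 fell, 89 together with 12 clone names and 394 with the block (231 rises, 163 falls), and 53 were called without non-induced array 3 and 47 without induced array 3. Median scaling ended the calls of Hey1, Dtx1, Emid2, Gja4, Hlx1, Mesp1, Dcxr, Dpp4, Agtrl1, Corin, Jag1, Lum and Gsc (0.0726 to 1.00). Other processing ended Hey1, Dtx1, Emid2, Gja4, Dcxr, Dpp4, Agtrl1, Lum and Gsc (0.0514 to 0.223), and omission of the dim arrays Dcxr, Dpp4, Agtrl1 and Gsc (0.105 to 0.313). Notch1 (1.08 ± 0.32, adjusted p = 0.168 without and 0.00256 with the block, sets 1.44, 0.92 and 0.88) and Foxc2 (1.24 ± 0.37, 0.168 and 0.0210) were called with the block, Foxc2 also without non-induced array 1 (0.0293). Hes1 (0.39), Hey2 (0.53), Runx1 (0.16), Gata1 (-0.57), Gata2 (-0.08), Tal1 (-0.14), Etsrp71 (-0.62) and Itga2b (-0.03) were not called.

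**Figure D3:**
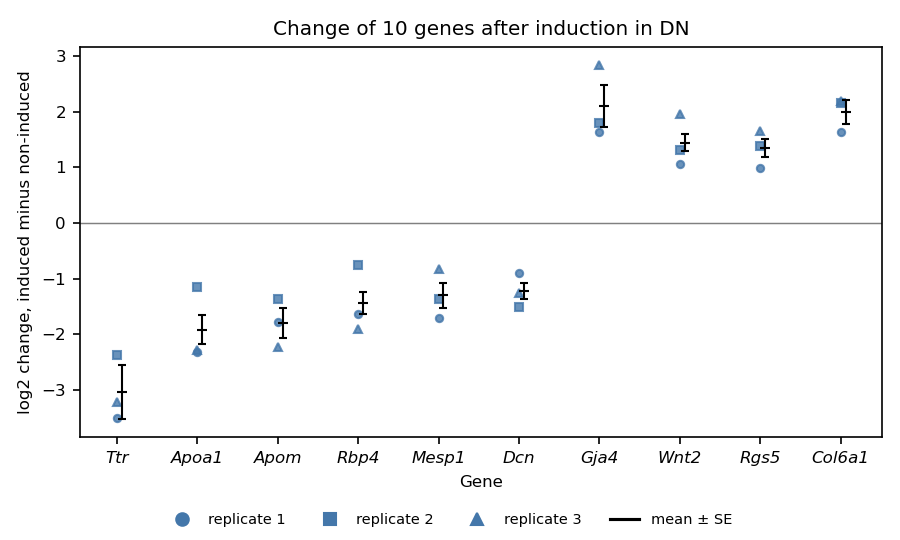
Log2 change on induction in DN (vertical axis) of 10 named genes (horizontal axis); points are the changes in the 3 replicate sets and bars the mean ± SE of the fit. Ttr lay at -3.51, -2.37 and -3.22 and Rbp4 at -1.64, -0.76 and -1.91.

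Notch targets rose in DN with 4 of 14 called and 5 adjusted over the list alone. Their mean was 0.88 and their median 0.52, and the set means were 0.81, 0.79 and 1.03 (adjusted p = 3.18e-09). Endoderm genes fell with 3 of 13 called and 6 adjusted over the list alone. Their median was -0.92 and the set means were -1.04, -0.77 and -1.20 (adjusted p = 8.00e-10). Both held with an estimated correlation (adjusted p = 0.00354 and 0.0195), the endoderm call not with the estimate and the block together (0.0879). Arterial genes rose with 3 of 19 called and 5 adjusted over the list alone, including the Notch ligand Jag1 (1.13 ± 0.23, detected on 1 of 3 non-induced arrays), a call kept only without non-induced array 1 or induced array 3 (otherwise 0.0512 to 0.0718). Their median was 0.53 and the set means were 0.49, 0.65 and 0.64 (adjusted p = 6.07e-06, but adjusted p = 0.0795 with an estimated correlation). Mesenchyme and matrix genes rose by the test, with 1 of 21 higher and 2 lower, 6 and 2 adjusted over the list alone. Their median was 0.34 and the set means were 0.41, 0.26 and 0.42 (adjusted p = 0.00725, but adjusted p = 0.0949 with an estimated correlation). Their members included the matrix proteoglycans Dcn (-1.22 ± 0.14, 5.82e-05) and Lum, at least 1.46-fold lower, a call kept only without non-induced array 1 (otherwise 0.0585 to 0.194). Primitive streak genes fell with 2 of 10, as many adjusted over the list alone, including the organizer gene Gsc (-1.17 ± 0.23, detected on 2 of 3 induced arrays), lost without non-induced array 1 or 3 or induced array 2 (0.0682 to 0.0873). Their median was -0.31 and the set means were -0.30, -0.43 and -0.23 (adjusted p = 0.0197, but adjusted p = 0.382 with an estimated correlation). That last call was lost without non-induced array 1 (0.270), induced array 2 (0.290) or induced array 3 (0.0696), under median scaling (0.0609), without the dim arrays (0.371) and under other processing (0.0605 to 0.268).

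On average over the 4 fractions, Hey1, a direct Notch target, rose by 2.50 ± 0.30 (adjusted p = 3.99e-05) and the matrix genes Emid2 and Col5a1 by 2.42 ± 0.26 and 1.99 ± 0.18 (the latter 8.49e-07). Igfbp5 rose by 2.26 ± 0.25, Aldh1b1 by 2.01 ± 0.18, the cell cycle inhibitor Cdkn1c by 1.49 ± 0.20 (9.69e-05), Mcpt1 by 1.45 ± 0.09, Nrarp by 1.43 ± 0.17, Mcpt4 by 1.34 ± 0.18 and Chst2 by 1.31 ± 0.12. Dtx1 (1.26 ± 0.19, 0.000518), Foxc2 (1.02 ± 0.18, 0.00205) and Heyl (0.54 ± 0.09, 0.00137) rose and Etsrp71 fell (-0.84 ± 0.18, 0.00827). The largest falls were the immediate early genes Fos (-2.04 ± 0.54, 0.0452, sets -1.33, -4.15 and -0.64) and Fosb (-1.85 ± 0.49, 0.0453), Spink3 (-1.93 ± 0.35), Ttr (-1.59 ± 0.24), Agtrl1 (-1.05 ± 0.16), Pde4dip (-1.04 ± 0.19), Dcxr (-1.04 ± 0.16), Oit3 (-0.99 ± 0.17), the water channel Aqp8 (-0.97 ± 0.18) and the cartilage protein Matn1 (-0.97 ± 0.18). Fos was lost without 19 and Fosb without 17 of the 24 arrays, at adjusted p up to 0.0901 and 0.0937. Mcpt4 and Heyl were undetected in 6 of the 8 groups, Mcpt1 in 5, Oit3 in 4, Aldh1b1 and Foxc2 in 3, Emid2 in 2 and Chst2, Dtx1, Ttr and Agtrl1 in 1, so their averages are differences of fitted means and no folds. In all 197 genes rose and 88 fell, 285 together with 48 clone names, and 1242 with the block (686 rises and 556 falls, 55.2% rising), which added Notch1 (0.44 ± 0.16, adjusted p = 0.179 without and 0.00542 with it) and Hes1 (0.59 ± 0.19, 0.123 and 0.00462). Median scaling gave 57 rises and 14 falls, 80.3% against 69.1% rising. It ended the calls of Fos, Fosb, Agtrl1 and Pde4dip and of Cdkn1a, Phlda3, Bax, Ccng1, Fbn1 and Col4a2 below (0.0573 to 0.637). Without the dim arrays Fos, Fosb, Spink3, Aqp8, Etsrp71, Bax, Fbn1 and Col4a2 were lost (0.0568 to 0.349), and without the low-weight arrays Fos (0.0580). Other processing ended Fos, Fosb, Bax and Col4a2 (0.0511 to 0.119).

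**Figure D4:**
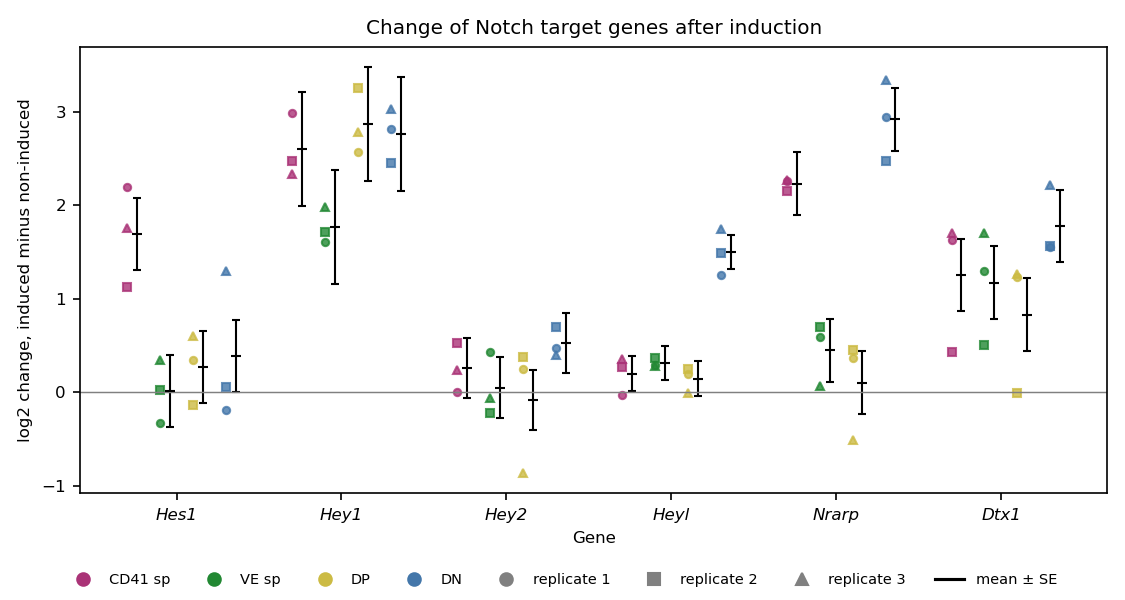
Log2 change on induction (vertical axis) of 6 Notch target and pathway genes (horizontal axis) in the 4 fractions, given by colour; points are the changes in the 3 replicate sets and bars the mean ± SE of the fit. Heyl was undetected in 6 of the 8 groups, so its changes are fitted differences and no folds.

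Notch targets rose on average with 7 of 14 called and 9 adjusted over the list alone, including Trib2 (0.90 ± 0.16). Their mean was 0.61 and their median 0.53 and the set means were 0.63, 0.51 and 0.69 (adjusted p = 1.22e-09). Arterial genes rose with 5 of 19, 8 adjusted over the list alone, including Jag1 (0.81 ± 0.11, undetected in 2 of the 8 groups). Their median was 0.24 and the set means were 0.45, 0.40 and 0.50 (adjusted p = 8.90e-08). Targets of p53 fell with 4 of 16, 7 adjusted over the list alone, namely the cell cycle inhibitor Cdkn1a (-0.74 ± 0.13), Phlda3 (-0.71 ± 0.12), the cell death gene Bax (-0.64 ± 0.17) and Ccng1 (-0.42 ± 0.08, other probes -0.74 and -0.70), the Bax call being lost without 17 of the 24 arrays (0.0525 to 0.0891). Their median was -0.28 and the set means were -0.41, -0.33 and -0.26 (adjusted p = 3.64e-08). These 3 calls held with an estimated correlation (adjusted p = 0.00238, 0.0417 and 0.00949), the arterial one not with the estimate and the block together (0.150). Mesenchyme and matrix genes rose with 3 of 21 called, 6 higher and 2 lower adjusted over the list alone, including Fbn1 (0.83 ± 0.17) and Col4a2 (0.69 ± 0.17). Their median was 0.15 and the set means were 0.28, 0.25 and 0.29 (adjusted p = 0.00243, but adjusted p = 0.0690 with an estimated correlation). Endoderm genes fell with 3 of 13 called, 1 higher and 4 lower adjusted over the list alone. Their median was -0.24 and the set means were -0.45, -0.32 and -0.44 (adjusted p = 0.000389, but adjusted p = 0.145 with an estimated correlation). Immediate early genes fell with 2 of 13, as many adjusted over the list alone. Their median was -0.38 and the set means were -0.70, -1.17 and 0.07 (adjusted p = 5.36e-05, but adjusted p = 0.306 with an estimated correlation). In the plot of list means, the calls for immediate early genes in CD41 sp (mean -0.52, adjusted p = 0.0322 without and 0.0683 with the block) and Hox genes on average (mean -0.13, 0.0492 and 0.108) ended with the block.

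**Figure D5:**
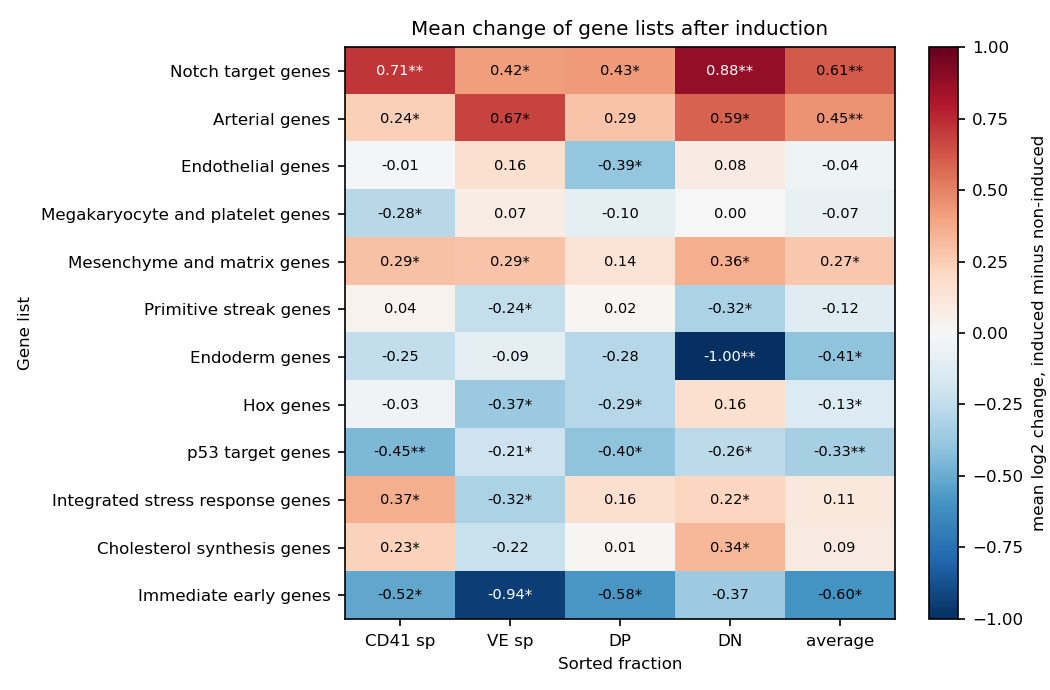
Mean log2 change on induction of 12 gene lists (vertical axis) in the 4 fractions and on average (horizontal axis), given by colour and number; 1 star marks lists that passed at the preset correlation and 2 stars those that also passed with an estimated one. Notch targets had means of 0.71 in CD41 sp, 0.42 in VE sp, 0.43 in DP and 0.88 in DN.

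The response to induction differed among the 4 fractions for 14 genes by the interaction test, and for 202 with the block, which added Heyl (adjusted p = 0.0512 without and 0.00271 with it), Notch1 (1.00 and 0.0274) and Hes1 (0.999 and 0.0437). Mcpt1 led (adjusted p = 1.42e-07), with detection on 1 of 3 arrays in induced DP and none in induced VE sp, followed by Prkcb (6.41e-05). Prkcb rose by 2.43 ± 0.19 in VE sp and was at least 1.44-fold higher in DN (adjusted p = 0.0759 without and 0.0213 with the block). The signalling ligand Wnt2 (0.00335) rose by 1.44 ± 0.16 in DN (detected on 1 of 3 non-induced arrays) and was undetected in CD41 sp and VE sp. Dcn (0.00515) changed by -1.22 ± 0.14 in DN and was undetected elsewhere, where no fall could show. Corin (0.00464) rose at least 4.34-fold in VE sp and by 1.49 ± 0.27 in DN, Npr3 (0.00705) by 2.84 ± 0.31 in VE sp, and Col6a1 (0.00748) by 1.99 ± 0.21 in DN and at least 1.5-fold in VE sp. Rgs5, a pericyte marker (0.0195), rose by 1.34 ± 0.16 in DN and at least 1.18-fold in VE sp. The VE sp call for Col6a1 was lost without non-induced array 1 or 2 or induced array 2 or 3 (0.0984 to 0.127), and that for Rgs5 without induced array 3 (0.0845). Nrarp (0.0121) rose by 2.23 ± 0.34 in CD41 sp and 2.92 ± 0.34 in DN against 0.45 and 0.10 in VE sp and DP, and Mcpt4 (0.0230) completed the 10 smallest p-values. The other 4 were added after seeing their values. Rgs1 (0.0232, -1.13 in CD41 sp) was undetected in VE sp and DN. Rbp4 (0.0304, -1.44 in DN) and Irx6 (0.0479, at least 1.54-fold in VE sp) were undetected elsewhere. The adhesion scaffold Nedd9 (0.0479) rose by 1.66 ± 0.25 in VE sp. Calls lost without 1 of the 24 arrays were Irx6 (20 arrays, up to 0.142), Nedd9 (19, up to 0.118), Rbp4 (12, up to 0.162), Mcpt4 (non-induced CD41 sp 1 to 3, DP 2 and DN 3 and induced CD41 sp 1, up to 0.0777), Rgs1 (non-induced CD41 sp 1 and 3, DP 2 and DN 3 and induced CD41 sp 1 and 2, up to 0.115) and Rgs5 (non-induced DP 2 and DN 3 and induced CD41 sp 1, DN 2 and DN 3, up to 0.0618). The count was 8 without non-induced DP array 2, non-induced DN array 3 or induced CD41 sp array 1. Median scaling kept only Mcpt1, Prkcb and Col6a1 (others 0.136 to 1.00). Without the dim arrays Dcn, Npr3, Col6a1, Rgs5, Rgs1, Rbp4, Nedd9 and Irx6 were lost (0.0614 to 0.234), without the low-weight arrays Mcpt4, Rbp4, Nedd9 and Irx6 (0.0579 to 0.120). All but Mcpt1, Prkcb, Wnt2 and Corin were lost under other processing (0.0506 to 0.281).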

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

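Both tests on Mcpt1 and Mcpt4 and the test of endoderm cell shares with background subtracted were written after results were seen, the test of mast cells replacing an earlier one over all measured mast cell genes with the same outcome, and the other tests weighed here were written beforehand. The response to induction differed among fractions, by the adjusted p of the interaction test, for Mcpt1 (1.42e-07), Prkcb (6.41e-05), Wnt2 (0.00335), Corin (0.00464), Dcn (0.00515), Npr3 (0.00705), Col6a1 (0.00748), Nrarp (0.0121), Rgs5 (0.0195), Mcpt4 (0.0230), Rgs1 (0.0232), Rbp4 (0.0304), Nedd9 (0.0479) and Irx6 (0.0479). Non-induced Dcn, Rgs1 and Rbp4 were detected only where they fell, so their test cannot show a different response. Of 100 ways of swapping induced and non-induced arrays within same-numbered pairs, the real one included, 14 gave as many as 14 genes, with up to 51 in another, so chance is not excluded for this count. A swap in only some fractions turns the shared response into a difference between them. Outside the genes tested, the 2 probes of the Notch target Hes5 had mean signals of 6.79 (SD 1.75) and 6.33 (SD 1.37) in induced DN, where they were detected on 2 of 3 arrays. They were also detected on 1 of 3 induced CD41 sp arrays and on 0 of the non-induced ones.

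Mcpt1 and Mcpt4, proteases of mast cells, rose after induction in CD41 sp and DN. Mast cells in the induced fractions would bring their other abundant transcripts, but the 10 mast cell genes not detected on all 3 non-induced arrays (7 of them on none) had median changes of -0.0083 ± 0.0459 in CD41 sp and -0.0105 ± 0.0392 in DN, and 0 of them were detected on all induced arrays. Both probes reading 1 transcript would keep their difference equal in the 2 fractions, yet Mcpt1 less Mcpt4 was larger in induced CD41 sp than in DN by 1.19 ± 0.111 (1.11, 1.05 and 1.41 in the 3 sets). Whether the mast cell probes respond to their transcripts was not tested. Induction of these genes by ICN1 or doxycycline in other cells stays open as a hypothesis.

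Endoderm genes fell in induced DN. Dim induced arrays of replicate 2 do not account for it, since the mean change in replicates 1 and 3 alone was -1.118 ± 0.0774. Fewer endoderm-type cells would lower all members alike, and the changes of 7 members spread by an SD of 1.105 against a mean SE of 0.348, which met the bound set beforehand against this explanation. That bound was wrong for members near background, such as Fgg (5.13 before induction, -0.12), which cannot fall far, and with background subtracted the log2 shares kept by 6 members spread by 0.7436 against a mean SE of 0.380. Of these members 5 kept 10.6% to 20.3% of their signal (Ttr, Apoa1, Spink3, Rbp4 and Amn) and Hnf4a 45.0%, so fewer such cells and lower expression per cell may both apply and cannot be told apart.

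Responses to induction resembled each other between fractions, which deviations of a shared culture could produce. Across genes, changes of different fractions correlated at a mean of 0.234 within sets and 0.160 between sets (0.0346 to 0.228 over 6 fraction pairs). Genes are not independent replicates. Deviations of a set cannot reach other sets, so they are not the whole resemblance. For CD41 sp and VE sp they may be (0.210 within, 0.0346 between). Within 1 fraction the changes correlated between sets at 0.382 in CD41 sp, 0.457 in VE sp, 0.259 in DP and 0.557 in DN.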

How the results depend on the processing

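Omission of the dim or low-weight arrays was chosen after seeing the data, and the others were planned. Counts follow the order CD41 sp, VE sp, DP, DN, average for induction, then CD41 sp against DN, VE sp against DN, DP against DN, DP against VE sp and CD41 sp against DP, then the interaction. The counts were 9, 109, 13, 89, 285, 1498, 2361, 2114, 977, 1183 and 14. With the replicate set as a fixed block they rose to 87, 418, 155, 394, 1242, 2903, 4205, 3779, 2062, 2569 and 202, and as a random block to 101, 388, 129, 298, 1125, 2762, 4105, 3613, 1969, 2438 and 179. Calls of named genes and described lists that the fixed block changed are given with the results. Median scaling gave 3, 23, 3, 34, 71, 864, 1098, 1225, 397, 543 and 3. Only probes detected on all 24 arrays, fewer genes by construction (6542), gave 3, 19, 4, 10, 116, 697, 1311, 1089, 428, 691 and 0 (151 at an unadjusted limma p under 0.05), and 46 instead of 95 list calls between fractions. Array weights gave 36, 204, 36, 137 and 535 for induction and 51 for the interaction. The interaction count was 7 without background correction, 8 with normexp and an offset of 50, 9 with cyclic loess, 24 without filter, 9 from the authors' processed table and 25 with trend and robust moderation, and the DP count was 8 with cyclic loess. The share of higher genes was 58.4% with cyclic loess instead of 50.4% in VE sp against DN, and 53.1% on probes detected on all arrays instead of 44.8% in CD41 sp against DN. At an adjusted p under 0.01 there were 50 in VE sp, 5 in DP, 46 in DN, 140 on average, 1556 in VE sp against DN, 647 in DP against VE sp, 736 in CD41 sp against DP and 7 in the interaction. A 2-fold threshold left 36 on average and 1447, 1344 and 777 in VE sp against DN, DP against DN and CD41 sp against DP. Fitting only the 6 arrays compared, fewer samples by construction, gave 1, 10, 0 and 9 in the 4 fractions, with 382 genes in DP at an unadjusted limma p under 0.05. Without the dim arrays there were 15 in CD41 sp and 71 in VE sp, and without the low-weight arrays 18 in CD41 sp and 5 in DP. With an estimated correlation 4 of 41 list calls for induction and 53 of 95 between fractions passed, while fry called 8 and 105. Leaving out 1 array or 1 replicate set gave 1 to 10, 6 to 80, 0 to 9, 13 to 75 and 27 to 296 for induction, 755 to 1405, 1392 to 2242, 1170 to 1888, 544 to 917 and 516 to 1112 between fractions, 2 to 19 for the interaction, and 30 to 47 and 94 to 97 list calls. The 0 was DP without set 3 (581 at an unadjusted limma p under 0.05). Apart from the settings with fewer genes or samples, the cause was not tested.

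For named genes and lists, no alternative reversed a call. Over all alternatives, calls of the 254 named gene results held in 6568 fits and were lost in 669, those of the 57 described lists held in 1325 and were lost in 68, and those of the interaction held in 430 and were lost in 160. The 157 gene results not called stayed so in 4223 cases and were called in 87. Without 1 array, 52 named results lost their call and 4 gained one. Other probes of the named genes, 69 compared, went the opposite way in 0 cases, but 13 were not called and 24 gave changes smaller by over 1.5 times. Signals near background limit what can be seen of genes with low expression.

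The 10 splits of 3 against 3 are too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes in each of the 9 comparisons, and the highest other counts were 0, 2, 2 and 15 for induction in CD41 sp, VE sp, DP and DN and 0, 1, 0, 1 and 0 between fractions. Among the 4 splits that part all 3 same-numbered pairs, the highest other count was 0 in all 9. Of 100 swaps within pairs, the others gave at most 114 genes on average (real 285) and 35 list calls for induction (real 41). Swaps break deviations shared in a set, so chance is not excluded. Of 100 reassignments within sets, the real one included, 2 gave as many as the 95 list calls between fractions (highest other 96). The medians of the others were 0 genes, 19 list calls for induction and 77 between fractions. These can hold real calls, and the totals say nothing of single list calls.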

Other observations

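The gene lists were fixed before any value was seen and picked for description afterwards, and the tests of the Notch1 increments and of the DP shift were written before their results were seen. Pluripotency genes were lower in non-induced CD41 sp than in DN with 12 of 18 members, 12 lower and 1 higher adjusted over the list alone, among them Dppa5 (-4.64 ± 0.52) and the stem cell regulators Pou5f1 (-2.72 ± 0.34, detected on 1 of 3 CD41 sp arrays), Nanog, at least 3.96-fold lower, and Esrrb, at least 3.74-fold lower. Their median was -1.64, or -1.20 with undetected members at their bound, and the set means were -1.30, -1.82 and -1.14 (adjusted p = 3.62e-07). The call held with an estimated correlation (adjusted p = 0.0493) but not with the estimate and the block together (0.0712).

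Angiogenic sprouting genes were higher in non-induced VE sp than in DN with 6 of 13 members and lower with 1, as many adjusted over the list alone, including the growth factor Pdgfb (4.53 ± 0.34, detected on 2 of 3 DN arrays) and the VEGF receptor Flt1 (4.46 ± 0.31). Their median was 0.61 and the set means were 1.04, 1.69 and 1.17 (adjusted p = 0.000703). The call held with an estimated correlation (adjusted p = 0.0287) but not with the estimate and the block together (0.0528). In DP they were lower than in VE sp with 7 of 13, 9 adjusted over the list alone, including the vessel-remodelling ligand Agpt2 (-2.91 ± 0.46) and the tip cell gene Esm1 (-2.46 ± 0.35, detected on 1 of 3 DP arrays). Their median there was -1.30 and the set means were -0.98, -1.54 and -1.30 (adjusted p = 1.25e-08, and 0.00162 with an estimated correlation).

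Equal extra Notch1 signal in every fraction, added to unequal starting levels, could give log2 changes that differ as those of Notch1 did, a difference called by the interaction test only with the block (adjusted p = 1.00 without and 0.0274 with it). The linear increment was 29.3 ± 5.87 in CD41 sp, 135 ± 16.3 in DN, 144 ± 359 in VE sp and -99.6 ± 27.9 in DP, and the value in DP is one that this hypothesis forbids. A second hypothesis was that induced DP cells moved from the VE sp towards the CD41 sp profile, although the call for endothelial genes there (1 of 32 members called) was itself lost (adjusted p = 0.139 with an estimated correlation). The 100 genes higher in VE sp than in CD41 sp had a mean change of -0.22 in DP (67 negative) and 0.21 in DN, and the 100 lower genes -0.01 in DP. Its lowest adjusted p was 0.357 with an estimated correlation, which met what had been written beforehand against it, but a p that misses the threshold excludes nothing and the hypothesis stays open.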
